A study of Homo sapiens with 6 samples.

How the data were processed

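Total RNA had been amplified and biotin-labelled with a TotalPrep kit and hybridised to Illumina bead arrays, per the labels' protocols. The log2 bead signals analysed here were normalized by the authors before deposit. Their sorted values were equal on all 6 arrays to within 0.00049, as quantile normalization leaves them, while the background treatment and the rule that kept these probes are not stated. The deposited comparison table holds log2 fold changes and, per the file headers, a p-value and an adjusted p-value per probe made by the authors with a test that is not stated. The submitters' processing notes name limma with no role. These p-values matched an unpaired limma fit of the deposited values to within 0.00441 in natural log units, and 1670 probes passed in that table, 810 higher and 860 lower.

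The design written before the data were examined called for background correction and quantile normalization of raw signals with detection calls. The columns of raw signals and detection p-values, and the normalized per-array columns of the comparison table, carry codes that match no sample label. These 18 columns were not used, and no mapping was guessed. limma was fitted to the authors' normalized log2 values instead, and no detection filter could be applied. Signal over background is unknown here, and folds of genes near background may be understated.

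Probes were named by the deposited Entrez identifiers (10977 probes) or by accession (11), with current symbols from a GRCh38.p14 gene table, and 32 of 11020 stayed unnamed. No positions are given because the probes' genome build is not stated in the sources used here. Of 1452 genes with several probes, the probe with the highest mean signal stood for the gene, which gave 9215 genes. limma 3.58.1 in R 4.3.3 was fitted with 1 coefficient for the group, with moderated variances and Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. The sources do not state that replicates were separate cultures, so p-values measure the spread between these samples. Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1 made the remaining tables and figures.

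Gene lists were fixed from general knowledge before the data were examined, 24 in number. Those reported here covered reported miR-155-5p targets, the study's own genes, tight junctions, adherens junctions, focal adhesion, leukocyte adhesion and chemokines, NF-kB, interferon, barrier transporters, endothelial identity, 3 sets of other cell types (mural and fibroblast, leukocyte, neural), cell cycle, p53, BACH1 and NRF2, cholesterol, unfolded protein and stress response, hypoxia, TGF-beta, small RNA processing, heat shock and cytosolic ribosomal proteins. The 21 lists with at least 5 measured genes, apart from the study's own, were tested with limma's camera at a preset correlation of 0.01. P-values were adjusted over lists, and fry and camera with an estimated correlation were run beside it. The study's genes also sat in tested lists. CLDN1 was among tight junctions, ANXA2 among adherens junctions, and DOCK1 and SDCBP in focal adhesion. Lists added after the data were seen were histone genes, MHC class I, complement and extracellular matrix. SRF and MRTF contractile genes, and YAP1 with its targets, were also added then.

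The genes named are the 12 with the largest log2 fold change each way among called genes whose groups did not overlap, the study's genes, up to 4 members per list with the smallest p, known miR-155 targets, and further list members as examples. Alternatives run were the mean of all probes, each probe on its own, a trended and robust variance, array weights, the replicate number as a block, leaving out each array, an adjusted p under 0.01, the authors' comparison table, and, added after the data were seen, cyclic loess, centring on the brightest 10% of genes and omission of the dimmest 25% of genes. A simulation of 9215 genes with the same spread and independent noise changed 67, 67 and 66 genes by 1.2-fold, 1.5-fold and 2-fold. This fit recovered 44.8%, 95.5% and 98.5% of these changes, and 9 of 168 calls (5.36%) were false. The measured data held more calls (1411), which loosens the adjusted cutoff, so these shares need not hold there.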

Results

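Messenger RNA was measured on Illumina bead arrays in hCMEC/D3 cells, an immortalized human brain microvascular endothelial line that serves as a culture model of the blood-brain barrier. One group of 3 samples had been transfected with 30 nM of pre-miR-155, a synthetic precursor of the inflammation-linked microRNA miR-155. The other group of 3 samples had been transfected with a scrambled RNA, whose dose the labels do not state. The values were log2 bead signals that the authors had already normalized, with a median of 8.68 on every array. The 11020 probes of the value table named 9215 genes. Arrays of one group correlated across genes at r between 0.9964 and 0.9976, and arrays of different groups at r between 0.9914 and 0.9941. The first principal component, with 58.9% of the variance, separated the groups. On it pre-miR-155 replicate 1, at 5.57, lay nearer to the scrambled arrays (-7.14 to -8.19) than replicates 2 and 3 (8.58 and 9.27). The number of arrays limits the precision of every value below.

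The comparison asked which transcripts of brain endothelial cells respond to raised miR-155. CFB, a protease of the alternative complement pathway, rose 2.73-fold in pre-miR-155 cells, from 10.16 ± 0.06 to 11.61 ± 0.05 on the log2 scale (mean ± SD, n = 3 per group). TAGLN, the actin-binding protein transgelin, fell by 1.87 on the log2 scale, a 3.67-fold change, from 11.11 ± 0.10 to 9.24 ± 0.26. A second, dimmer TAGLN probe fell by 1.01. With limma and an adjusted p under 0.05, 1411 of 9215 genes changed (15.3%), 715 higher and 696 lower. Most changes were small, with a median fold size of 1.21 for genes called higher and a similar one for genes called lower. At least 2-fold changes were called for 12 genes higher and for TAGLN alone among those lower, and at least 1.5-fold changes for 72 genes higher and 15 lower. The groups did not overlap in 2946 genes (32.0%), against 10% by chance, and 1368 of the called genes were among these. The count of genes changed in pre-miR-155 against scrambled cells was 812 without scrambled replicate 3 and 938 without pre-miR-155 replicate 3.

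**Figure D1:**
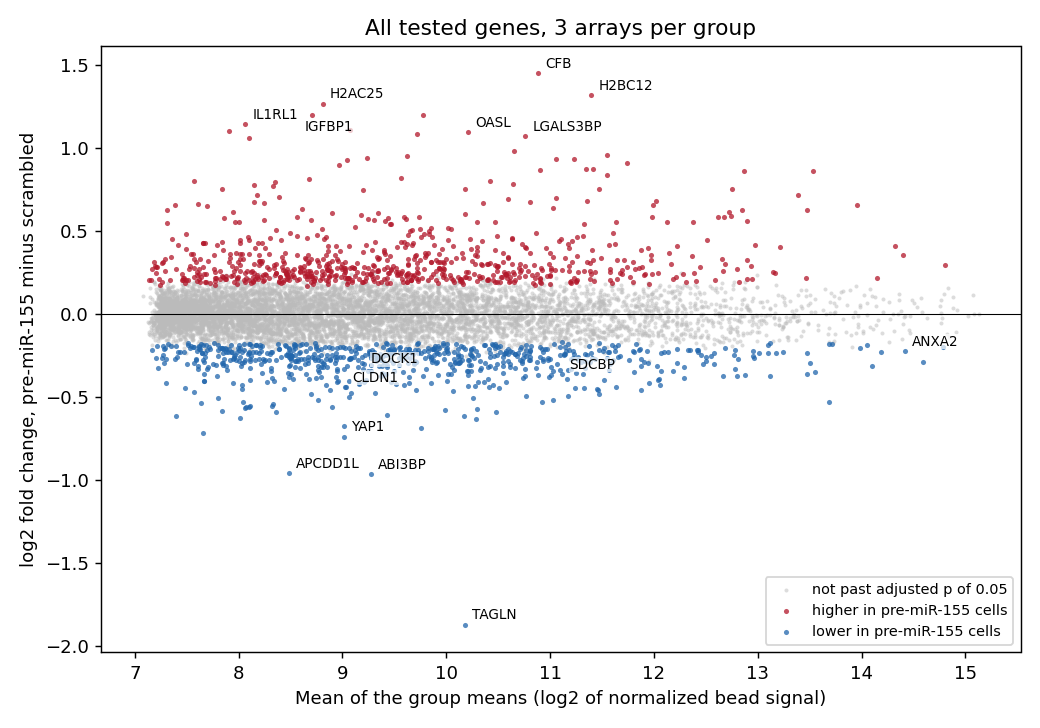
Log2 fold change of each of the 9215 tested genes (vertical axis, pre-miR-155 minus scrambled) against the mean of both group means (horizontal axis, log2 of normalized bead signal). Red points are the 715 genes called higher and blue points the 696 called lower, grey points did not pass an adjusted p of 0.05, and TAGLN at -1.87 lies far below all other genes.

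Beyond CFB, histone genes stood high among the transcripts that rose most. H2BC12 rose 2.49-fold (log2 fold change 1.32 ± 0.06 SE), H2AC25 2.41-fold, H2AC18 2.29-fold and the linker histone gene H1-2 2.16-fold. Called histone probes of one family shared at most 20 of 50 bases with each other, but they were not compared with the transcripts of other histone genes, so single histone genes are uncertain. C1R, the protease of the first complement component, rose 2.15-fold, and IL1RL1, the receptor of interleukin-33, 2.21-fold. IGFBP1, a secreted binder of insulin-like growth factors, rose 2.30-fold, with an SE of 0.06 on the log2 scale and an adjusted p of 5.83e-10. OASL, an interferon-induced relative of the oligoadenylate synthetases, rose 2.14-fold, the secreted galectin-3 binding protein LGALS3BP 2.10-fold and otoferlin (OTOF) 2.12-fold. On their second, dimmer probes the log2 fold changes of OASL and IL1RL1 were 0.61 and 0.69, under a 2-fold rise. NOSTRIN, which controls the trafficking of endothelial nitric oxide synthase, rose 2.08-fold with a wide spread in pre-miR-155 cells (8.63 ± 0.48, SD, against 7.57 ± 0.08, n = 3), where replicate 1 stood at 8.07 and the others at 8.95 and 8.86. By the rule that chose them, all 12 genes named here were above every scrambled array in all 3 pre-miR-155 arrays. None lost its call in any of the 6 fits that left out 1 array. The call of NOSTRIN ended when the variance was fitted with a trend and robust moderation (adjusted p = 0.0779), and its adjusted p over 14 alternatives ran from 7.27e-12 to that value.

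After TAGLN, the genes that fell most included secreted, cytoskeletal and signalling proteins. ABI3BP, an extracellular matrix protein, fell by 0.97 on the log2 scale (SE 0.13), and APCDD1L, a relative of a Wnt inhibitor, fell by 0.96 (SE 0.11). YAP1, the transcriptional coactivator of the Hippo pathway, fell by 0.74 (SE 0.10), a 1.67-fold change with an adjusted p of 8.45e-05. TMSB15A, an actin-sequestering thymosin, fell by 0.72, parathymosin (PTMS) by 0.69 and DPYSL3 by 0.68. SULF1, which trims heparan sulfate, and RAB11FIP1, an effector of recycling endosomes, each fell by 0.63. LITAF and ID2, an inhibitor of basic helix-loop-helix transcription factors, each fell by 0.62, and CRIP1 fell by 0.61. All 12 genes were below every scrambled array in all 3 pre-miR-155 arrays, again by the rule that chose them. They kept their calls in the 6 fits without 1 array. In several the pre-miR-155 arrays were uneven, with SDs of 0.42 for ABI3BP, 0.37 for SULF1, 0.33 for APCDD1L and 0.31 for YAP1 against 0.13, 0.08, 0.05 and 0.06 in scrambled cells. With a trended, robust variance the calls of ABI3BP and SULF1 ended (adjusted p = 0.0630 and 0.0951), while leaving out pre-miR-155 replicate 1 gave their lowest adjusted p, 1.09e-10 and 1.92e-08.

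Of the genes that the study is known to have followed up from these arrays, all 4 were called lower. CLDN1 (Entrez gene 9076), which encodes the tight junction protein claudin-1, fell by 0.44 on the log2 scale (SE 0.07), from 9.24 ± 0.05 to 8.80 ± 0.12 (SD, n = 3). SDCBP (Entrez gene 6386), the adaptor syntenin-1, fell by 0.36 (SE 0.07), and DOCK1 (Entrez gene 1793), an activator of the small GTPase RAC1, fell by 0.33 (SE 0.06). ANXA2 (Entrez gene 302), the membrane-binding annexin A2, fell by 0.22 (SE 0.07) on its brightest probe, near the top of the scale at 14.53 in scrambled cells, and its groups overlapped there. Its other probes gave falls of 0.46 and 0.37 on that scale. Adjusted p-values were 1.99e-04 for CLDN1, 0.00202 for SDCBP, 0.00100 for DOCK1 and 0.0497 for ANXA2. All 4 were also lower when adjusted over the list alone. Since the study chose these genes on these samples, their direction is not independent evidence. The call of ANXA2 was lost in 4 of the 6 fits without 1 array, without pre-miR-155 replicates 2 and 3 and scrambled replicates 2 and 3, and its adjusted p over 14 alternatives ran from 6.86e-04 to 0.259 without pre-miR-155 replicate 3. After cyclic loess it was 0.0711.

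Tight junction genes moved in both directions. Of 17 measured, 4 fell, 2 rose and 11 did not pass. CLDN1 and CGNL1, which encodes the junction-tethered paracingulin, fell by 0.44 and 0.38, and TJP1, the scaffold ZO-1, fell by 0.19. MARVELD2, the tricellular junction protein tricellulin, fell by 0.18. CLDN5, the main claudin of brain endothelium, rose 1.17-fold (12.10 ± 0.03 to 12.32 ± 0.10, SD, n = 3), and the endothelial adhesion molecule ESAM rose 1.18-fold. Adjusted over the list alone, 5 were lower and 3 higher. The list median was -0.07, and limma's camera, which compares a list with all other genes, gave an adjusted p of 0.361. Its adjusted p over 16 alternatives ran from 0.0349 with fry, which asks only whether members move one way on balance, to 0.615. No member was called higher, and 2 were called lower, without pre-miR-155 replicate 3 or without scrambled replicate 3, and none higher without pre-miR-155 replicate 2. Without scrambled replicates 1 or 2, 1 was higher. CLDN5, ESAM and TJP1 each lost their calls in 4 of the 6 fits without 1 array and MARVELD2 in 5, with the highest adjusted p-values of 0.0995, 0.124, 0.154 and 0.119 all without pre-miR-155 replicate 3.

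Among adherens junction and endothelial contact genes, 6 of 21 fell, 1 rose and 14 did not pass. The actin crosslinkers ACTN1 and ACTN4 fell by 0.35 and 0.26, CDH2, which encodes N-cadherin, fell by 0.27, and CTNNB1, which encodes beta-catenin, fell by 0.27. The scaffold IQGAP1 and ANXA2 also fell, whereas PECAM1, a homophilic adhesion receptor of endothelial borders, rose 1.28-fold. CDH5, which encodes VE-cadherin, had a log2 fold change of -0.00 and was not called. The same counts were found when adjusted over the list alone. The list median was -0.03, and camera gave an adjusted p of 0.185, with a range over 16 alternatives from 0.01002 with fry to 0.334. CTNNB1 lost its call without scrambled replicate 3 (adjusted p = 0.0581) and IQGAP1 in 4 fits, with up to 0.184 without scrambled replicate 2. The number lower was 3 without scrambled replicate 3, and the number higher was 2 without pre-miR-155 replicate 1.

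Focal adhesion, integrin and matrix contact genes leaned lower, with 7 of 36 lower, 2 higher and 27 not past the threshold. ITGAV, the integrin alpha-V chain, fell by 0.34, PARVA, a parvin of the integrin-linked kinase complex, fell by 0.36, and TNS3, a tensin, fell by 0.34, beside ACTN1, DOCK1 and SDCBP. ITGA5, the fibronectin receptor chain, rose 1.26-fold. Adjusted over the list alone, 9 were lower and 2 higher. Without pre-miR-155 replicate 2 or scrambled replicate 3, 1 was higher. The list median was -0.08 and 29 members were negative. Camera placed the list below other genes (adjusted p = 0.00226). That call was lost with an estimated correlation between members (adjusted p = 0.125). The list holds DOCK1 and SDCBP, which the study chose on these samples, and it was not tested without them.

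**Figure D2:**
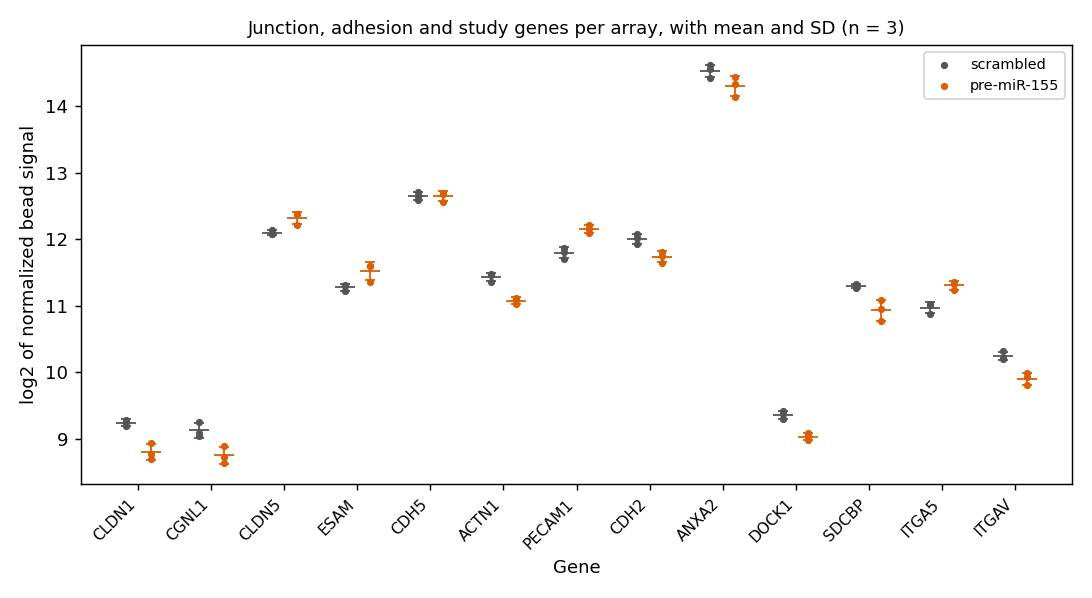
Log2 of normalized bead signal (vertical axis) of 13 junction, adhesion and study genes in each scrambled (grey) and pre-miR-155 (orange) array, with horizontal bars for the mean and whiskers for the SD (n = 3). CLDN1 lies at 9.24 in scrambled and 8.80 in pre-miR-155 cells, CLDN5 at 12.10 and 12.32, and the points of CDH5 overlap.

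Reported direct targets of miR-155-5p were examined as a list of 56 genes, of which 41 were measured. LDOC1, a nuclear regulator of transcription, fell by 0.36 (SE 0.06), SMAD5, a transducer of bone morphogenetic protein signals, fell by 0.24, and PKIA, an inhibitor of protein kinase A, fell by 0.18. Of the 2 genes that rose, the Toll-like receptor adaptor MYD88 rose 1.15-fold. The remaining 36 did not pass, and the counts were the same when adjusted over the list alone. Log2 fold changes of other known targets were 0.08 ± 0.07 (SE) for BACH1, 0.12 ± 0.06 for INPP5D, 0.08 ± 0.06 for CEBPB and -0.19 ± 0.09 for ETS1, none of them called. SOCS1 and the miR-155 host gene MIR155HG were not tested here. The list median was -0.06, with 28 of 41 members negative. Camera gave an adjusted p of 0.0605, and over 16 alternatives it ran from 0.01002 with fry to 0.230 with an estimated correlation, passing also without pre-miR-155 replicate 3 (0.0470) and without scrambled replicate 1 (0.0478). LDOC1 kept its call in every fit without 1 array. MYD88 lost its call in 4 of the 6 fits, with up to 0.111 without scrambled replicate 3, SMAD5 in 3, with up to 0.0876 without scrambled replicate 2, and PKIA in 6, with up to 0.116 without pre-miR-155 replicate 3. None was higher without pre-miR-155 replicate 3 or scrambled replicate 3 and 1 was in each other such fit, and 1 was lower without pre-miR-155 replicate 2, scrambled replicate 2 or scrambled replicate 3.

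Interferon-stimulated genes rose together. Of 39 measured, 36 rose and none fell, and their median fold size was 1.47. OASL rose 2.14-fold, XAF1, a partner of the apoptosis inhibitor XIAP, 1.91-fold and MX2, a dynamin-like antiviral GTPase, 1.91-fold. A second, dimmer XAF1 probe rose by 0.50 on the log2 scale. RSAD2, the antiviral enzyme viperin, rose 1.69-fold from 9.81 ± 0.06 to 10.56 ± 0.03 (SD, n = 3). Among the transcription factors of the pathway, IRF7 rose 1.69-fold, STAT2 1.31-fold and IRF9 1.26-fold. IFI6, BST2 and IFI27 were not called. Adjusted over the list alone, 37 were higher. Camera gave an adjusted p of 1.36e-43, and it was the 1 list of the 21 tested whose call held with an estimated correlation (adjusted p = 0.0382). Each of the 6 fits without 1 array called 36 members higher.

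Transcripts of the TGF-beta and BMP response leaned lower, with 9 of 17 lower, none higher and 8 not past the threshold, 5 of them positive. ID1, ID2 and ID3, immediate targets of BMP receptors, fell by 0.43, 0.62 and 0.46. BAMBI, a decoy receptor, fell by 0.59, and TAGLN fell by 1.87. The list median was -0.23. Camera gave an adjusted p of 1.30e-04, and the call was lost with an estimated correlation (adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 11 were lower and 2 higher. Cytosolic ribosomal protein genes also leaned lower, 11 of 31 with none higher and a median of -0.13, among them RPS23 and RPL14, which fell by 0.47 and 0.48. A second, dimmer RPL14 probe fell by 0.23. Their camera adjusted p was 2.29e-04, and 0.190 as an adjusted p with an estimated correlation. Ribosomal protein genes have many processed pseudogene copies, so single members are uncertain. Adjusted over the list alone, 13 were lower. Without pre-miR-155 replicates 2 or 3 the ribosomal count was 7, and without scrambled replicate 3 it was 5.

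Endothelial identity genes leaned higher, with 5 of 24 higher, none lower and a median of 0.10. MMRN1, a multimerin of endothelial cells and platelets, rose 1.48-fold and PECAM1 1.28-fold. ANGPT2, a context-dependent ligand of the TIE2 receptor, rose 1.76-fold, with a spread of 0.45 in pre-miR-155 cells against 0.15 in scrambled cells (SD, n = 3). TIE1 rose 1.18-fold. Camera gave an adjusted p of 0.00203, lost with an estimated correlation (adjusted p = 0.354), and 7 were higher when adjusted over the list alone. The call of ANGPT2 ended with a trended, robust variance (adjusted p = 0.125, the highest over 14 alternatives whose lowest was 1.33e-09). TIE1 and ESAM lost theirs in 4 of the 6 fits without 1 array, with up to 0.0906 and 0.124 without pre-miR-155 replicate 3. The number higher was 8 without pre-miR-155 replicate 1 and 3 without pre-miR-155 replicate 3, scrambled replicate 2 or scrambled replicate 3.

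Among markers of other cell types, TAGLN fell and ACTA2 rose 1.22-fold of 8 pericyte, smooth muscle and fibroblast genes (camera adjusted p = 0.213). When adjusted over the list alone, 2 of them were higher and 2 lower. ACTA2 lost its call in 2 fits, with up to 0.0799 without pre-miR-155 replicate 2. All 3 measured leukocyte markers rose, CD68 1.33-fold, CD74 1.27-fold and CD14 1.17-fold, and the same 3 passed when adjusted over the list alone. The call of CD14 was lost in 4 fits, with up to 0.105 without pre-miR-155 replicate 3. Both neural markers, MBP and TUBB3, had no call over all genes (log2 fold changes of -0.23 and -0.15), and both were lower when adjusted over the list alone. Neither the leukocyte nor the neural list had the 5 genes needed for a list test.

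Leukocyte adhesion molecules and chemokines split, with 3 of 15 higher and 4 lower, or 2 lower without pre-miR-155 replicate 3 or scrambled replicate 2. CCL5, a chemokine for T cells and monocytes, rose 1.98-fold (log2 fold change 0.99 ± 0.07, SE), while the neutrophil chemokine CXCL8 fell by 0.56 (SE 0.07). ICAM2 rose 1.33-fold and CX3CL1 1.33-fold, whereas VCAM1, a ligand of leukocyte integrins, fell by 0.27. ALCAM fell by 0.27 and IL32 fell by 0.21, and each was not called in 4 of the 6 fits without 1 array, with up to 0.122 for ALCAM without scrambled replicate 3 and 0.0641 for IL32 without scrambled replicate 1. The list median was -0.11 and its mean 0.01, with camera pointing down (adjusted p = 0.614), and 5 were higher and 5 lower when adjusted over the list alone. Of blood-brain barrier transporters and receptors, 5 of 22 rose and 6 fell. The glucose transporter gene SLC2A3 rose 1.30-fold and the prostaglandin transporter gene SLCO2A1 1.23-fold. ALPL, the tissue-nonspecific alkaline phosphatase, rose 1.74-fold, a call that ended with a trended, robust variance (adjusted p = 0.130, the highest over 14 alternatives whose lowest was 7.14e-10). The transferrin receptor gene TFRC fell by 0.40 and the fatty acid transporter gene SLC27A1 fell by 0.28. ABCB1, ABCG2 and SLC2A1 did not pass. Camera gave an adjusted p of 0.557 for the transporters, and 6 were higher and 9 lower when adjusted over the list alone. Without scrambled replicate 3, 3 were higher and 3 lower, and 3 were higher without pre-miR-155 replicate 3 or scrambled replicate 2.

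Of the 21 lists tested, 6 passed camera, 2 as higher and 4 as lower, and 1 of those lower is left out of this text. None of the lists that follow passed camera on all 6 arrays. S phase and mitosis genes had 4 of 37 lower and 1 higher (camera adjusted p = 0.109, and 0.0160 with fry). CDC20, the activator of the anaphase-promoting complex, was lower with a log2 fold change of -0.29. The number lower was 2 without pre-miR-155 replicate 3 and 1 without scrambled replicate 3, and none was higher in these fits or without scrambled replicate 1. Of 12 genes repressed by BACH1 or activated by NRF2, TXNRD1, which encodes thioredoxin reductase, fell by 0.45 (SE 0.06) and ABCC1 fell by 0.18, with a list adjusted p of 0.0522. That list passed with fry (adjusted p = 0.0135). Among the fits without 1 array it passed without scrambled replicate 2 (0.0465) and without scrambled replicate 3 (0.0323), and ABCC1 lost its call in 5. NF-kB feedback genes had 1 of 17 lower, TNFAIP8, which fell by 0.28 and lost its call without scrambled replicate 3 (adjusted p = 0.0827); the list adjusted p was 0.941. In the p53 list 1 of 16 rose, AEN (0.606 for the list), and AEN lost its call in 4 fits, with up to 0.179 without pre-miR-155 replicate 3.

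Hypoxia genes had 3 of 18 higher, among them adrenomedullin (ADM), which rose 1.32-fold, and 3 lower, among them ALDOA, which fell by 0.35 (list adjusted p = 0.9003). The hypoxia count lower was 5 without pre-miR-155 replicate 1 and 1 without pre-miR-155 replicate 2 or scrambled replicate 3. Unfolded protein and stress response genes had 1 of 19 higher and 2 lower, with ATF3 falling by 0.27 (0.941). Of these, 1 was lower without pre-miR-155 replicates 2 or 3 or scrambled replicates 1 or 3, and none was higher without pre-miR-155 replicates 2 or 3 or scrambled replicate 3. Cholesterol genes had 1 of 20 higher and 1 lower (0.263), the lower being MVD, whose call was lost in all 6 fits without 1 array. None was higher without pre-miR-155 replicates 2 or 3 or scrambled replicates 2 or 3. Of 12 heat shock genes HSPB1 fell by 0.23 (0.109), a call lost without pre-miR-155 replicate 3 and without scrambled replicate 3. Without scrambled replicate 1, 3 were lower and that list passed (0.0164). None of 15 small RNA processing genes was called (0.850), with a median of -0.01, a mean of 0.01 and camera pointing up. Adjusted over the list alone, counts differed in 3 of the lists from cell cycle onwards, with 3 lower for BACH1 and NRF2 genes, none for p53 and none lower for cholesterol genes.

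**Figure D3:**
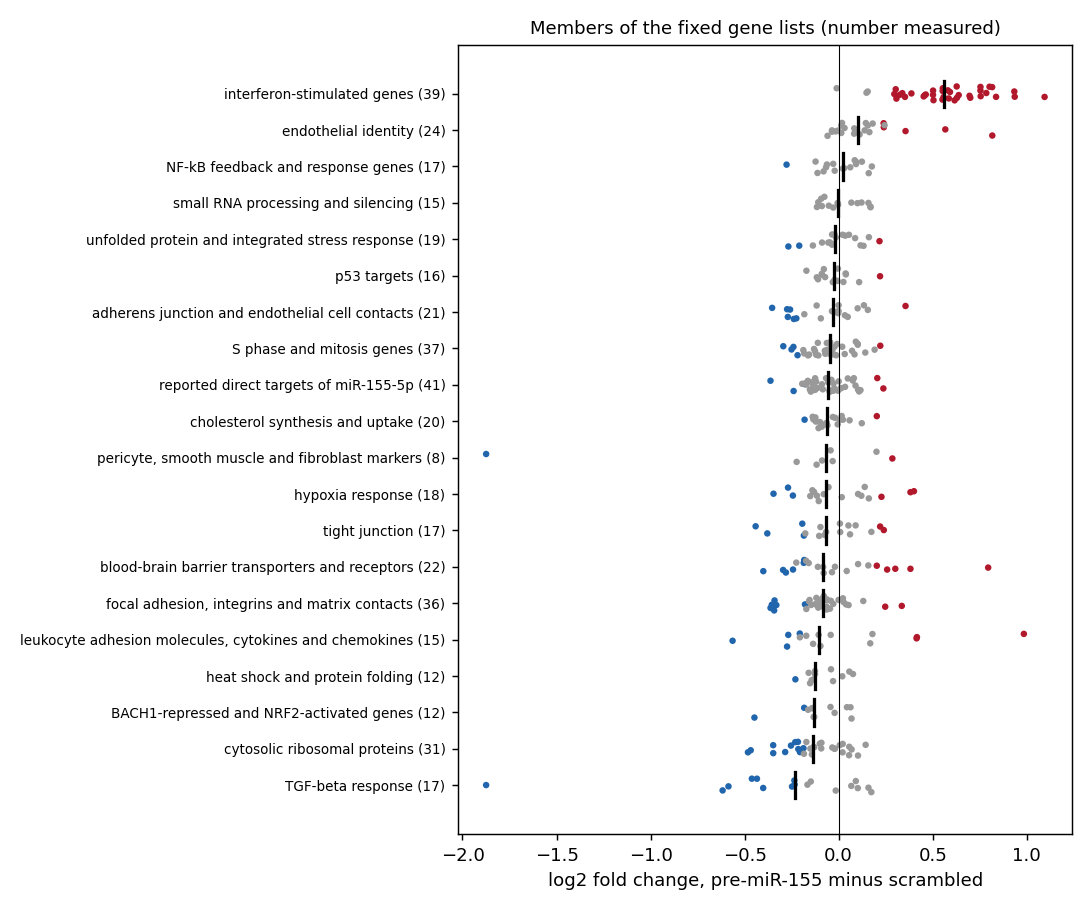
Log2 fold changes (horizontal axis, pre-miR-155 minus scrambled) of the members of 20 of the fixed lists with at least 5 measured genes, named on the vertical axis with the number measured. Red points were called higher, blue lower and grey neither, and black bars mark the list median, which was 0.56 for interferon-stimulated genes and -0.23 for the TGF-beta response.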

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

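The number of genes changed was 766 at an adjusted p under 0.01, 354 lower and 412 higher. Leaving out each array in turn gave 812 to 1391 changed, 440 to 710 higher and 372 to 681 lower, each lowest without scrambled replicate 3. The other fits gave 1134 to 1735 changed genes. Camera with an estimated correlation passed 1 list, with an adjusted p of 0.125 for focal adhesion. Fry passed 11, with 0.01002 for miR-155 targets, 0.0349 for tight junctions and 0.01002 for adherens junctions. It also passed mural and fibroblast (0.0117), BACH1 and NRF2 (0.0135) and cell cycle genes (0.0160). Leaving out 1 array gave 0.0470 to 0.126 for miR-155 targets.

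The direction of lists far from the threshold turned. NF-kB genes turned with array weights (0.922) and without the dimmest 25% of genes (0.910), and ran from 0.821 to 0.968 without 1 array. Hypoxia genes turned with fry (0.961) and ran from 0.752 to 0.966 without 1 array, stress response genes from 0.692 to 0.966, and leukocyte adhesion genes from 0.343 to 0.966. BACH1, never called, ran from -0.0034 to 0.12 on the log2 scale.

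With the replicate number as a replicate block, 1134 genes were called, 1129 of them also without it, and 7 of 112 named genes lost their call. The labels do not say whether equal numbers mark paired cultures, and 1 of 6 samples correlated best with its own number.

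Not run, because raw and detection columns match no sample label, were no background correction, another offset, median scaling, detection filters, the authors' per-array table and a slide block. The series matrix is the source itself. Tests of 3' UTR seed matches were not run, as no sequences were given. Signal over background is unknown, so folds of dim genes stay limited. The cause of the differences between settings was not tested.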

Other observations

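The 6 gene lists of this part and the tests of S phase genes and of RNA responses other than to the miR-155 sequence were chosen after the results were seen.

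Histone genes were among those that rose most, with 10 of 25 higher and 1 lower. They belonged to the H1 family (among them H1-2), the H2A family (H2AC25, H2AC18, H2AC6, H2AC20), the H2B family (H2BC12, H2BC5, H2BC21) and the H4 family (H4C8). H2BC21 and H3-3A, the gene called lower, lost their calls in 1 and 4 of the 6 fits without 1 array, with adjusted p-values of up to 0.0687 without scrambled replicate 3 and 0.0953 without pre-miR-155 replicate 1. MHC class I and peptide loading genes rose in 9 of 16, among them HLA-F by 0.96, PSMB9 by 0.70 and TAP1 by 0.62 on the log2 scale, and PSMB9 and TAP1 also belong to the interferon list. HLA genes have close paralogs whose probes were not compared, so single HLA genes are uncertain. Of 8 complement genes, CFB, C1R and C1S rose, and the inhibitor CD59 fell. Of the 2 complement genes lower, 1 was lower without pre-miR-155 replicate 3 or scrambled replicate 3. Camera gave adjusted p-values with an estimated correlation of 0.0223 for histone genes, 0.0223 for MHC class I and 0.0334 for complement. These were adjusted over the added lists alone, apart from the 21 fixed lists tested, so the adjusted p-values of the 2 sets cannot be ranked together. As the lists of this part were drawn up after their genes were seen to change, their p-values describe the lists and do not test them.

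Secreted matrix genes fell in 10 of 27 with none higher, among them FBLN5 by 0.50 and FBLN1 by 0.54. The matrix count was 6 without pre-miR-155 replicate 3. Contractile genes driven by SRF and MRTF fell in 7 of 14, among them TAGLN, MYL9, TPM1 and TAGLN2. In that list 1 was higher, or none without pre-miR-155 replicates 2 or 3. Each fit without 1 array called 5 or 6 of its members lower. TPM4 lost its call in all 6 of these fits and FHL2 in 4. Of 20 genes in the YAP list, which holds YAP1 itself beside its targets, 6 fell and 1 rose. Those that fell included YAP1 by 0.74, AXL by 0.53 and CRIM1 by 0.34, and IGFBP3 rose by 0.61. The targets CCN2 and ANKRD1 were not called. The count of YAP list genes lower was 4 without pre-miR-155 replicate 3 or scrambled replicate 2. Adjusted p-values with an estimated correlation, again over the added lists alone, were 0.0223, 0.0281 and 0.0334 for these lists.

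The rise of interferon-stimulated genes did not rest on one array, since at least 36 members were called higher in each fit without 1 array. The median log2 fold change of 0.56 cannot be told apart from a response to the transfected RNAs for a reason other than the miR-155 sequence, because each RNA was given to 1 group only. Sensing of double-stranded RNA by the cells would be a cause of that kind, whereas an action of miR-155 would be a cause through its sequence. Neither was tested, and the dose of the scrambled RNA is not stated.

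Beside the histone genes, 17 S phase genes did not rise as a set, with a median log2 fold change of -0.034 (SE 0.038) and 11 negative. That SE measures the spread over genes, which need not be independent. A small rise in the share of cells in S phase therefore stays open. GC content stays open, since its removal left 101% of the histone median but hardly moved it, from 0.135 to 0.136, and the 25 members went both ways. One transcript read by several probes stays open. Called probes shared at most 22 of 50 bases between families and 20 within them, but a transcript can pair with unlike probes at different positions, and no transcript sequences were given. Less of the stem-loop binding protein SLBP, which matures histone transcripts, stays open and cannot be told apart, with a log2 fold change of -0.14 (95% interval -0.33 to 0.06) that was not called.

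Probes that hold the miR-155-5p seed site GCATTA, 53 genes, had a mean log2 fold change of 0.003 ± 0.025 (SE), and 69.3% of the other hexamers of the same base composition had a lower mean. Pairing with the seed cannot be told apart here from no effect, since the probes hold 50 bases each and not whole 3' UTRs. These genes were not lower, so there was no shift for GC content to explain, and the value of 0.0051 after its removal decided nothing.

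The real grouping of the 6 arrays called 1411 genes, 696 lower and 715 higher, and the highest count of any other split was 0, so 1 of the 10 splits reached each of the 3 values. A number of 10 splits cannot give a share under 0.05.

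On the linear scale, genes called without pre-miR-155 replicate 1 lay there by a median of 25.2% of the way to the scrambled mean among genes lower, 25.8% among other genes higher and 15.1% among interferon genes. The corresponding values were 5.29%, 4.47% and -8.31% in replicate 2, and 2.46%, -0.366% and -6.73% in replicate 3. The gaps between genes lower and interferon genes were 10.2, 13.6 and 9.19 percentage points. Choosing genes by calls from the other arrays by itself draws the left-out array toward scrambled, more so where changes are small. The gaps can arise from that selection, so no conclusion is drawn from them.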
